A study of Mus musculus with 6 samples.

How the data were processed

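The samples were 6 RNA-seq libraries of EGFP-positive cells from the calvaria of CX3CR1-EGFP mice, 3 after LPS with CTLA4-Ig and 3 after LPS with control IgG. Groups were taken from the treatment label and replicate numbers from the titles. Per the labels' protocols, total RNA was extracted with a miRNeasy kit and libraries were made with a stranded TruSeq mRNA kit. Per the submitters' processing notes, TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cuffnorm 2.2.1 were used with the mouse build mm10 (GRCm38). Their settings, the annotation and the use of strand in counting are not given in the sources used here. The deposited values are FPKM, 1 value per gene name and library, as scaled between libraries by the authors. FPKM sums ran from 726360 to 851710 per library. Names of microRNA, snoRNA and similar genes (760 names) held 2.61 to 4.34% of the sum, and several stood at 0 in some libraries and at high values in others. Division by a very short transcript length can give such values from few fragments.

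FPKM tables hold no read counts. The depth was estimated from low values, which are spaced by what 1 fragment is worth in a gene: over 190 genes this gave 9040000, 8510000 and 10400000 fragments for CTLA4-Ig libraries 1, 2 and 3 and 8620000, 9370000 and 8980000 for control libraries 1, 2 and 3. These are in the authors' scaling. Of 13827 low values tested, 50.84% were whole multiples of the gene's smallest value within a tolerance of 0.02, so no counts were rebuilt and no count test was run. The lowest depth was 0.819 of the highest, so the precision of low genes was similar in the 6 libraries.

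Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), in genes with a mean of at least 1 FPKM over the 6 libraries, with 1 factor for the group. P-values were Benjamini-Hochberg adjusted, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, for lists with at least 5 measured members, and adjusted over the 42 lists tested. They were written before the data were examined, as were these tests, the rule for named genes and the alternatives other than the 2 named below as added. The 45 lists hold 927 distinct genes, of which 921 were matched to the files, 22 of them through an older symbol in the RefSeq gene table of assembly GRCm38.p6. Coordinates come from the same table, in which Sept5 was not matched. Camera was run again with a correlation estimated from the data, and fry, a rotation test of whether a list's genes move on balance one way, was run beside it. Scores of a list are the mean log2 value of its measured members, compared with a two-sided exact permutation test. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for depth and figures.

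Named genes followed a fixed rule. Where fewer than 5 genes passed, it took the 10 genes per direction with the smallest unadjusted p among those whose libraries did not overlap. Cx3cr1, Cd80, Cd86, Csf1r and Tnfrsf11a were always included. From each list past the threshold it took the 4 members with the smallest unadjusted p, and from each other list 2. This named 120 genes, of which the text gives a part. S100a8, S100a9, Camp, Padi4, Mpo, Elane, Prtn3, Ctsg, Mmp8, Csf3r, Cxcr2, Plaur, Lcn2, Gm9781, Mir1896, Snord16a, Snord32a, Saa3 and Chi3l3 were named after their values were seen.

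The test was checked on data simulated once as independent normal values, with the means and limma's moderated spreads of the 10865 genes, of which 200 were changed. It recovered 45% of genes changed by 0.5 on the log2 scale and 90% of genes changed by 1, and 7.53% of its calls were false. With no effect and independent genes camera called 0 lists, and with neutrophil markers shifted by 0.4 it called 1.

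The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, rescaling by the median of ratios, quantile normalization, no trend, a robust prior, array weights, a replicate block and leaving out each library in turn. After seeing the data, 2 were added: leaving out small RNA genes, and leaving neutrophil markers out of the other lists. Small RNA genes stayed in the main test, and 3 lists with fewer than 5 measured members (platelet, muscle and epithelial markers) were not tested. Reads were not analysed here.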

Results

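RNA was sequenced from 6 libraries of EGFP-positive cells sorted from the calvaria, the bones of the skull vault, of CX3CR1-EGFP mice. In these mice a green fluorescent protein marks cells that use the gene of the fractalkine receptor CX3CR1, which include monocytes and osteoclast precursors, the cells that fuse into bone-resorbing osteoclasts. The mice had received lipopolysaccharide (LPS), a bacterial outer membrane component that provokes inflammation and bone loss, at the periosteum of the calvaria. With it they received 10 mg/kg CTLA4-Ig in one group or whole human IgG in the control group, and cells were sorted 5 days later, with 3 libraries per group. CTLA4-Ig (abatacept) joins the outer domain of CTLA-4 to an antibody Fc part and binds CD80 and CD86 on antigen-presenting cells. The titles number the libraries as biological replicates, but no label says which animals each came from. The p-values of single genes therefore measure the spread between these libraries. Those of limma's camera at a preset correlation compare a list's genes with all other genes. They rest mainly on the spread over genes, and can be far smaller than 3 libraries per group could give. Each library listed 23284 genes in FPKM, fragment counts scaled for transcript length and library size. The spacing of low values put the depth at 8510000 to 10400000 fragments with CTLA4-Ig and 8620000 to 9370000 with control IgG, so the depths of the groups overlapped.

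The sorted cells carried transcripts of several myeloid cell types. S100a8, which encodes a calcium-binding protein abundant in neutrophils and monocytes, had the highest value of all genes in each of the 6 libraries. S100a8 and its partner S100a9 together made up 17.091, 21.871 and 19.995% of the FPKM sum with CTLA4-Ig and 14.218, 15.888 and 14.369% with control IgG. Csf1r, the receptor for the macrophage growth factor M-CSF (chromosome 18, 61105572 to 61131139, GRCm38), stood at 157 ± 15.4 FPKM with CTLA4-Ig and 162 ± 26.7 with control IgG (SD, n = 3). Cx3cr1, whose locus drives the reporter (chromosome 9, 120048683 to 120068296), stood at 22.4 ± 5.14 and 22.9 ± 10.1 FPKM (SD, n = 3). Tnfrsf11a, which encodes the osteoclast differentiation receptor RANK (chromosome 1, 105780673 to 105849444), was low in both groups, at 1.60 ± 0.144 and 1.81 ± 0.187 FPKM (SD, n = 3). Across genes, the correlation of log2 values between libraries was 0.9616 to 0.9729 within groups and 0.954 to 0.9706 between groups (Pearson's r; genes are not independent replicates).

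The comparison of CTLA4-Ig with control IgG asks which genes of these cells differ after the drug, and the study's title names cellular movement as the theme. The lists of neutrophil markers, of receptors for chemoattractants and of the actin cytoskeleton were higher on balance with CTLA4-Ig, and that of ribosomal proteins was lower. At a preset correlation between genes limma's camera gave them Benjamini-Hochberg adjusted p = 4.56e-08, 0.0122, 2.0e-04 and 4.5e-04, but with an estimated correlation each had an adjusted p = 0.7311 and 0 of 42 lists passed, as with limma's fry. Mmp9, a matrix metalloprotease made by neutrophils and osteoclasts (chromosome 2, 164940326 to 164955850), stood at 205 ± 27.6 FPKM with CTLA4-Ig against 101.5 ± 27.3 with control IgG (SD, n = 3), a log2 fold change of 1.04 ± 0.20 (SE). Ltf, which encodes the granule protein lactoferrin (chromosome 9, 111019292 to 111042766), stood at 3235 ± 631 against 1980 ± 386 FPKM (SD, n = 3), a log2 fold change of 0.71 ± 0.19 (SE). Fold changes are on the scale of log2(FPKM + 1), which understates those of low genes.

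No single gene passed the test. Of 10865 genes with a mean of at least 1 FPKM, limma called 0 at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.7196. At an unadjusted p under 0.05 there were 659 genes, 444 higher and 215 lower, where chance gives 543.2, and 347 without CTLA4-Ig library 2. In 1324 genes (12.2%) the libraries of the groups did not overlap, where chance gives 10%. In simulated data of this size the test recovered 45% of the genes changed by 0.5 on the log2 scale and 90% of those changed by 1. The simulation used independent genes and limma's moderated spreads, so it can overstate what the test finds in the real data. Mmp9, at a log2 fold change of 1.04, had an adjusted p = 0.7196 in limma, so changes of that size are not excluded.

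The genes below had the smallest unadjusted p among those without overlap, and their values are given as measured, not as calls. Fbxo10, which encodes a substrate receptor of a ubiquitin ligase (chromosome 4, 45034248 to 45084604), stood at 8.22 ± 0.788 FPKM with CTLA4-Ig and 4.64 ± 0.202 with control IgG (SD, n = 3), a log2 fold change of 0.71 ± 0.09 (SE). Cebpe, a transcription factor needed for late neutrophil granules (chromosome 14, 54710363 to 54712174), stood at 199 ± 25.7 and 138 ± 5.36 FPKM (SD, n = 3), a log2 fold change of 0.52 ± 0.10 (SE). The log2 fold change was 0.78 for Stap2, a signalling adaptor, 0.71 for the chitinase-like gene Chi3l1 and 0.68 for Timp2, an inhibitor of matrix metalloproteases. It was 0.50 for the antiproliferative gene Tob1, 0.47 for the septin gene Sept5, 0.44 for Rnf144a, 0.43 for Abtb1 and 0.38 for the aldehyde dehydrogenase gene Aldh2. On the lower side, the log2 fold change was -0.29 for Mrps36 and -0.30 for Mrpl47, which encodes a mitochondrial ribosomal protein. Klra2, of the Ly49 receptor family, had a log2 fold change of -0.45, Slc25a43 also -0.45, Tmem150b -0.42, Lztfl1 -0.34 and the noncoding Gm15987 -0.33. Naa25 had -0.30, Pigf -0.28 and Iars, an isoleucine tRNA ligase gene, -0.24. Klra2 has close relatives, and Fbxo10, Timp2, Pigf, Tmem150b and Gm15987 overlap other genes (Polr1e, Cep295nl, Rhoq, Brsk1 and Clec2g), so their values are uncertain where the authors' counting could split such reads.

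**Figure D1:**
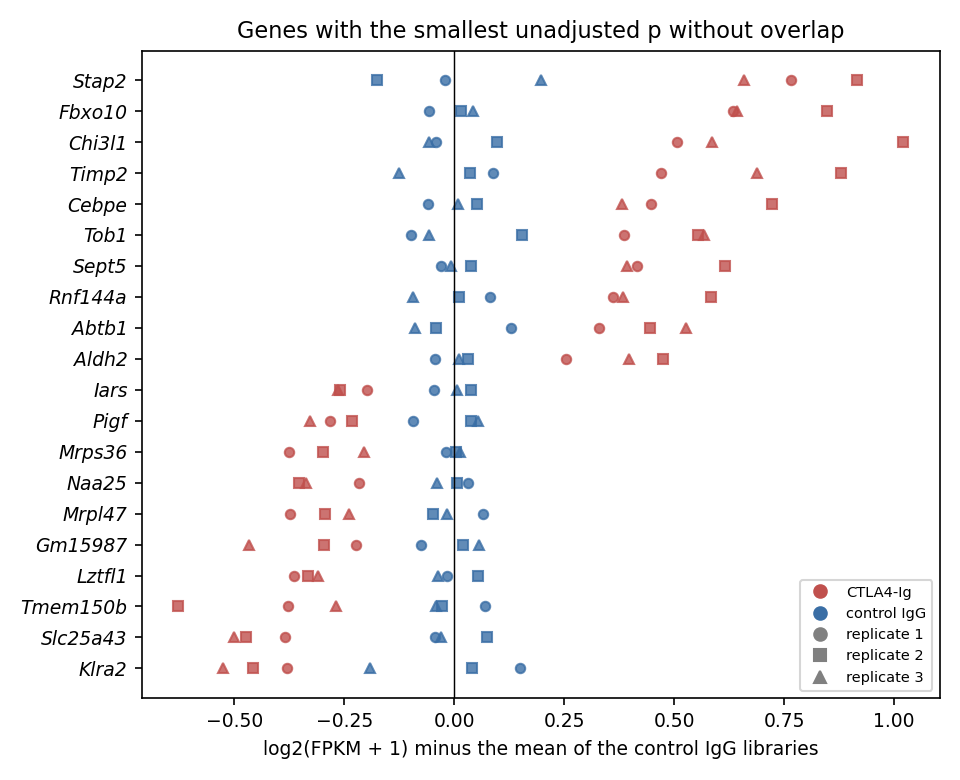
The 10 genes per direction with the smallest unadjusted p among genes without overlap; the horizontal axis gives each library's log2(FPKM + 1) minus the mean of the 3 control IgG libraries, one point per library. Stap2 shows the largest difference of these 20 genes, with a log2 fold change of 0.78, and 0 genes passed limma's Benjamini-Hochberg adjusted threshold.

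Neutrophil markers had the smallest p of the 42 gene lists tested. Of 19 measured markers, 15 had a positive log2 fold change, with a mean of 0.46, and limma's camera gave a Benjamini-Hochberg adjusted p of 4.56e-08 with a preset correlation between genes. With an estimated correlation the list had an adjusted p = 0.7311, and the same value held for each of the 7 lists past the threshold, so 0 lists passed in that way. Over all genes 0 members passed in limma, with 10 at an unadjusted p under 0.05, and 6 passed when adjusted over the list alone: Mmp9, Chi3l1, Ngp, Ltf, Padi4 and Camp. Ngp and Camp encode proteins of secondary granules, with log2 fold changes of 0.68 and 0.59, and Padi4, an enzyme that citrullinates histones, had 0.54. Markers of the primary granules, which form earlier in the lineage, had log2 fold changes of -0.01 for Mpo, -0.05 for Elane, -0.12 for Prtn3 and -0.13 for Ctsg. Mmp8 ranged from 138 to 553 FPKM over the control libraries and Csf3r from 83.7 to 87.7. The mean of the 19 markers was 9.93 ± 0.202 with CTLA4-Ig and 9.46 ± 0.257 with control IgG on the log2 scale (SD, n = 3; two-sided exact permutation p = 0.2, where 3 against 3 cannot go below 0.1).

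**Figure D2:**
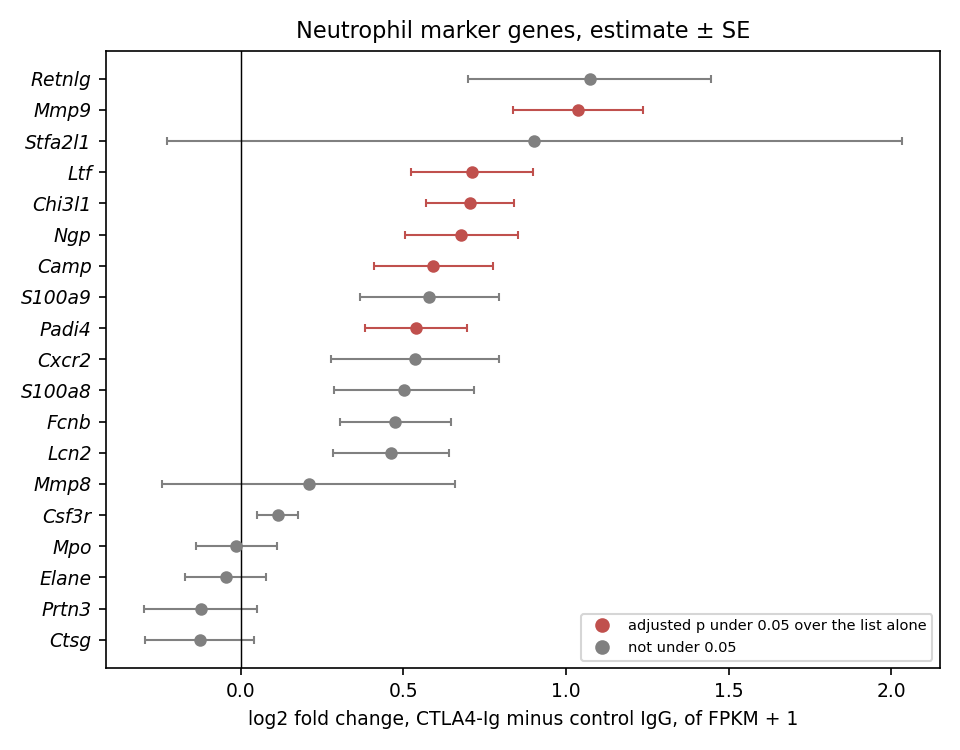
Log2 fold changes of the 19 measured neutrophil markers, CTLA4-Ig minus control IgG on the log2(FPKM + 1) scale, with bars of 1 SE from limma over 3 libraries per group. The 6 red points passed when adjusted over the list alone, and Mpo, Elane, Prtn3 and Ctsg lie just below 0.

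Among the lists on cell movement, the actin cytoskeleton and podosome list rose by a small amount. Of 45 measured members 36 had a positive log2 fold change, with a mean of 0.08 (limma camera, Benjamini-Hochberg adjusted p = 2.0e-04; adjusted p = 0.7311 with an estimated correlation). Over all genes 0 members passed in limma, with 7 at an unadjusted p under 0.05, all positive, and 0 passed when adjusted over the list alone. Rhoc, a small GTPase, had a log2 fold change of 0.64 ± 0.14 (SE), and the filament-severing gelsolin gene Gsn had 0.40 ± 0.10. Rac2, the Rac GTPase of blood cells, had 0.26 ± 0.07, and Vasp, which promotes filament growth, had 0.30 ± 0.09. The mean of the list was 7.38 ± 0.0427 with CTLA4-Ig and 7.29 ± 0.0160 with control IgG (SD, n = 3; two-sided exact permutation p = 0.1, the smallest possible). Neutrophil markers moved with the group by 0.46 on the log2 scale in the same libraries.

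Receptors for chemokines and other chemoattractants also rose as a list, with 18 of 24 members positive and a mean log2 fold change of 0.15 (limma camera, Benjamini-Hochberg adjusted p = 0.0122; adjusted p = 0.7311 with an estimated correlation). That estimate was -0.00413 between members, under the preset 0.01, so the higher p does not reflect a stronger correlation in this list. Unadjusted, limma's camera gave it p = 0.00156 at the preset correlation and 0.0247 with the estimate. Over all genes 0 members passed in limma, with 4 at an unadjusted p under 0.05, and 2 passed when adjusted over the list alone. These were Ltb4r1, the leukotriene B4 receptor, at 148 ± 10.1 FPKM against 116 ± 6.14 (SD, n = 3), and S1pr4, a sphingosine phosphate receptor, at 39.7 ± 1.80 against 32.3 ± 1.58. Ptafr, the receptor for platelet-activating factor, had a log2 fold change of 0.31, and Ccrl2 had 0.47. Without CTLA4-Ig library 3 the list's mean was 0.111 and its adjusted p 0.0759. One member, Cxcr2, is also in the neutrophil list, whose mean difference was 0.46. Without that member the receptor list had a mean of 0.131 (limma camera at the preset correlation, adjusted p = 0.0241).

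The other movement lists did not pass with all 6 libraries. Of 30 integrin and adhesion genes 16 were positive (limma camera, Benjamini-Hochberg adjusted p = 0.1257), 5 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone; without control library 3 the list's mean was 0.0719 (adjusted p = 0.0318). Itgb2, the β chain of leukocyte integrins, had a log2 fold change of 0.21 and the tetraspanin gene Cd9 0.63. Of 12 semaphorin, plexin and guidance genes 10 were positive (adjusted p = 0.2275 in limma camera), with 0.28 for Plxnc1 and 0.19 for Sema7a, and 0 passed when adjusted over the list alone, with 0 at an unadjusted p under 0.05. Without control library 3 the mean of the guidance list was 0.127 (adjusted p = 0.0299); with an estimated correlation and all 6 libraries it and the integrin list had an adjusted p = 0.7311. Of 13 chemokine genes 9 were positive (adjusted p = 0.8189 in limma camera), 1 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. Ccl8 had a log2 fold change of 1.08 and Ccl9 -0.27. Of 15 matrix proteases and inhibitors 8 were positive (adjusted p = 0.2979 in limma camera), and 3 passed when adjusted over the list alone: Timp2, Mmp9 and Plaur, the urokinase receptor gene, with a log2 fold change of 0.35 ± 0.09 (SE). The theme of movement was chosen by the study on these samples, so these lists are not independent evidence of its direction. Neutrophil markers, at a mean of 0.46, differed with the group beside each of these lists.

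**Figure D3:**
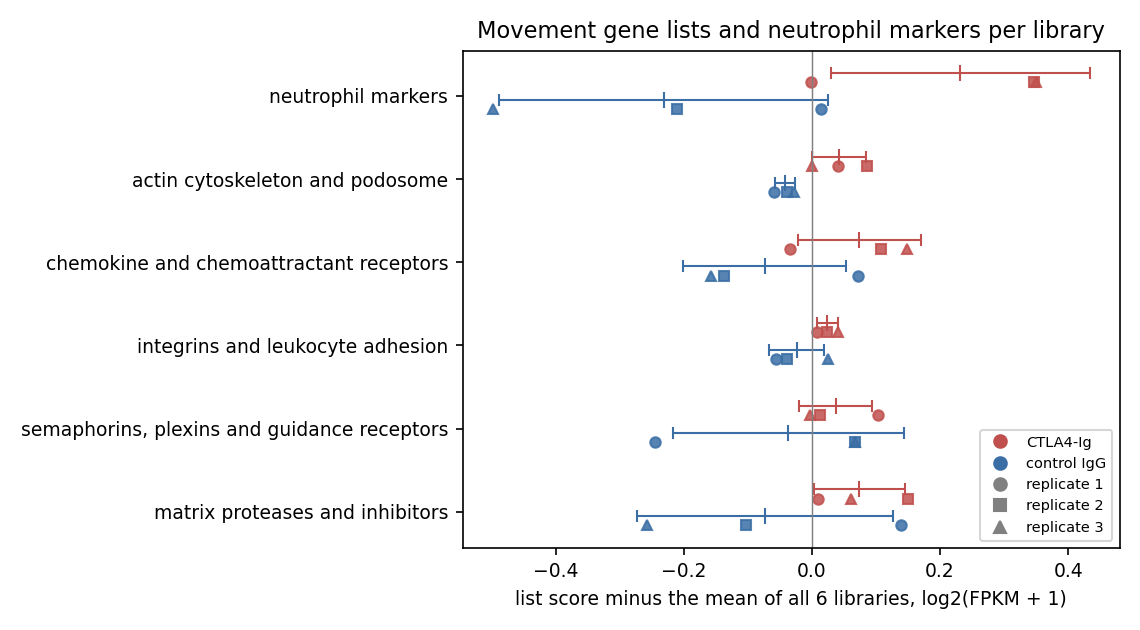
Mean log2(FPKM + 1) of each list's measured members per library, minus the mean of all 6 libraries, for neutrophil markers and 5 lists on cell movement; each point is a library and each bar the mean ± SD of 3 libraries. The groups do not overlap for the actin list, with means of 7.38 and 7.29, and they overlap for the other 5 lists.

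No list of osteoclast genes or of the ligands the drug binds passed the test. Of 21 osteoclast differentiation and resorption genes 14 were positive, with a mean log2 fold change of 0.10 (limma camera, Benjamini-Hochberg adjusted p = 0.4117). Mmp9 was the 1 member that passed when adjusted over the list alone, and Snx10, needed for the resorbing border of osteoclasts, had -0.20 ± 0.06 (SE). Of 24 regulators of osteoclast precursors 14 were positive (adjusted p = 0.4959 in limma camera), with -0.15 for Cebpa and 0.16 for Bcl6, and 0 passed when adjusted over the list alone, with 0 at an unadjusted p under 0.05. The log2 fold change was -0.11 ± 0.12 (SE) for Tnfrsf11a, -0.04 ± 0.13 for Csf1r and 0.05 ± 0.34 for Cx3cr1. Cd80 (chromosome 16, 38457430 to 38495958) stood at 4.83 ± 0.816 FPKM with CTLA4-Ig and 6.08 ± 2.76 with control IgG (SD, n = 3), a log2 fold change of -0.22 ± 0.27 (SE). Cd86 (chromosome 16, 36568956 to 36666158) stood at 8.22 ± 0.705 and 9.03 ± 0.489 FPKM (SD, n = 3), a log2 fold change of -0.12 ± 0.08 (SE). Of 16 costimulatory and inhibitory ligands 10 were positive (adjusted p = 0.4959 in limma camera), with 0.83 ± 0.35 (SE) for Tnfsf13b, the B cell survival factor BAFF, and 0.40 without control library 1, which stood at 10.1 FPKM against 27.9 and 24.3 in the other controls. Of 10 genes of tryptophan catabolism and the FOXO axis, which CD80 and CD86 signals can engage, 7 were negative (adjusted p = 0.4171 in limma camera), with -0.34 for Ahr and -0.35 for Kynu. Calcium signalling had 15 of 26 members positive (adjusted p = 0.4117 in limma camera), with 0.24 for the calcium channel gene Orai1 and 0.16 for Orai2.

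Inflammatory and antigen presentation genes went both ways. Of 25 inflammatory cytokine and LPS response genes 13 were positive (limma camera, Benjamini-Hochberg adjusted p = 0.4959), with 0.81 ± 0.24 (SE) for Il1rn, the antagonist of the IL-1 receptor, and 0.44 ± 0.15 for Il12a. Of 34 interferon-stimulated genes 21 were positive (adjusted p = 0.7741 in limma camera), with 0 at an unadjusted p under 0.05 in limma and 0 adjusted over the list alone. The direction of this list turned with single control libraries: its mean was -0.271 without control library 1 (adjusted p = 1.72e-08) and 0.240 without control library 3 (adjusted p = 9.24e-04), against 0.04 with all 6. Both calls are at the preset correlation, and with an estimated correlation and all 6 libraries the list had an adjusted p = 0.9692. MHC class II presentation had 11 of 14 members positive (adjusted p = 0.8632 in limma camera), with -0.20 for the cathepsin gene Ctss, and MHC class I 11 of 20 (adjusted p = 0.7741), with 0.21 for Tap2 and -0.18 for Pdia3. The mean of class I was -0.102 without control library 1 (adjusted p = 0.00690) and that of class II 0.204 without control library 3 (adjusted p = 0.0177), against -0.02 and 0.05 with all 6 (adjusted p = 0.9692 for both with an estimated correlation and all 6 libraries). Complement genes rose as a list, with 12 of 13 members positive and a mean log2 fold change of 0.29 (adjusted p = 0.00473 in limma camera; adjusted p = 0.7311 with an estimated correlation). Of the complement members, 2 had an unadjusted p under 0.05 in limma, 0 passed over all genes and 0 when adjusted over the list alone. The list shares 2 members with the chemoattractant receptors. Cd55 had 0.47, Itgam 0.21, C3 0.14 and C3ar1 0.33. The mean of the complement list was 0.179 without CTLA4-Ig library 3 (adjusted p = 0.0565), 0.170 without control library 2 (adjusted p = 0.113) and 0.427 without control library 1, and 0.205 with no filter on low values (adjusted p = 0.0606).

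Ribosomal protein genes fell as a list by a small amount, with 42 of 43 members negative and a mean log2 fold change of -0.11. Limma's camera gave a Benjamini-Hochberg adjusted p = 4.5e-04 at the preset correlation and 0.7311 with an estimated correlation. That estimate was 0.861 between members, so the 43 genes count as far fewer observations. The list score overlapped between the groups (two-sided exact permutation p = 0.3). In limma 0 members had an unadjusted p under 0.05, and 0 passed over all genes or when adjusted over the list alone. Rps25 stood at 1315 ± 110 FPKM against 1456 ± 168 (SD, n = 3), and the log2 fold changes were -0.14 for Rps25 and Rps2, -0.11 for Rpl8 and -0.12 for Rpl14. The list's mean was -0.0575 without control library 1 (adjusted p = 0.443), -0.0587 without CTLA4-Ig library 1 (adjusted p = 0.0501) and -0.0610 without CTLA4-Ig library 2 (adjusted p = 0.211), but -0.205 without CTLA4-Ig library 3 and -0.163 without control library 2. With array weights it was -0.0773 (adjusted p = 0.103). Immediate early genes rose as a list, with 17 of 20 members positive and a mean of 0.20 (adjusted p = 0.0282 in limma camera; adjusted p = 0.7311 with an estimated correlation). In that list 1 member had an unadjusted p under 0.05 in limma, and 0 passed over all genes or when adjusted over the list alone. Klf2 had a log2 fold change of 0.32, Rhob 0.15, Btg2 0.28 and Nr4a1 0.30. The mean turned to -0.0769 without control library 2, and it was 0.142 without CTLA4-Ig library 2 (adjusted p = 0.0857) and 0.104 without CTLA4-Ig library 3 (adjusted p = 0.285). It was 0.354 without CTLA4-Ig library 1, 0.332 without control library 1 and 0.344 without control library 3.

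Markers of other cell types were compared in the same way. Mast cell, basophil and eosinophil markers rose as a list, with 10 of 12 members positive and a mean log2 fold change of 0.28 (limma camera, Benjamini-Hochberg adjusted p = 0.0122; adjusted p = 0.7311 with an estimated correlation). In limma 0 members had an unadjusted p under 0.05, and 0 passed over all genes or when adjusted over the list alone. The basophil and mast cell factor gene Gata2 had 0.28, the eosinophil ribonuclease gene Ear1 0.76, Siglec5 0.31 and the eosinophil peroxidase gene Epx 0.57, where Ear1 has near-identical copies. Neutrophil markers, at a mean of 0.46, moved with the group beside this list and beside the complement, ribosomal and immediate early lists. The mean of the mast cell list was 0.131 without CTLA4-Ig library 3 (adjusted p = 0.437), 0.170 without control library 1 (adjusted p = 0.188), 0.165 with array weights (adjusted p = 0.164) and 0.222 with no filter (adjusted p = 0.0606). Classical monocyte markers had 12 of 14 members negative and a mean of -0.22 (adjusted p = 0.0589 in limma camera), with -0.38 for Ms4a4c and 0.47 for Cd177, which neutrophils also use. This list did pass with the replicate block (adjusted p = 0.00632), without small RNA genes (adjusted p = 0.0438) and without CTLA4-Ig library 1 (mean of -0.266), control library 2 (-0.270) or control library 3 (-0.327). It did not pass without control library 1. The list's score was 9.07 in that library, 8.63 and 8.52 in the other controls and 8.44 to 8.63 with CTLA4-Ig. With an estimated correlation and all 6 libraries the classical monocyte list had an adjusted p = 0.7311, as did the non-classical, macrophage, dendritic and NK cell lists, and T cell markers had an adjusted p = 0.9692. Non-classical monocyte markers had 12 of 15 positive (adjusted p = 0.1189), macrophage markers 11 of 17 (adjusted p = 0.1627) and dendritic cell markers 14 of 17 (adjusted p = 0.1175), all in limma camera. The non-classical list passed with the block (adjusted p = 0.0475), without CTLA4-Ig library 2 (mean of 0.242) and without control library 2 (0.212) or 3 (0.272), against 0.14 with all 6. The macrophage list passed without CTLA4-Ig library 1 (0.356 against 0.23) and the dendritic cell list without control library 2 (0.169) or 3 (0.236), against 0.11. Neither the non-classical nor the dendritic cell list passed without control library 1. The non-classical score was 4.17 in that library, 4.73 and 4.85 in the other controls and 4.52 to 4.99 with CTLA4-Ig. The dendritic cell score was 3.40 in that library, 3.91 and 4.05 in the other controls and 3.82 to 3.93 with CTLA4-Ig. NK cell markers had 9 of 12 negative (adjusted p = 0.1189 in limma camera), with -0.47 for Gzma and -0.30 for Gzmb. The NK cell list passed with array weights (mean of -0.251) and without CTLA4-Ig library 3 (-0.295) or control library 1 (-0.230), against -0.16 with all 6. T cell markers had 6 of 10 negative (adjusted p = 0.9446 in limma camera), and passed as lower without control library 1 (mean of -0.177). Over the 45 lists, 13 members in 5 lists passed when adjusted over the list alone, the fifth list being fibroblast markers with Gsn.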

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

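Leaving out small RNA genes, and leaving neutrophil markers out of the other lists, were chosen after seeing the data. The count of genes past the adjusted threshold was 0 with all 6 libraries under each alternative run in limma (11 besides the leave-one-out fits), with 562 to 904 genes at an unadjusted p under 0.05. With 1 library left out the count ran from 0 to 6, with 0 to 3 higher and 0 to 3 lower, and the largest came without CTLA4-Ig library 3. Of the genes called in those fits, all but Gm9781 are microRNA or snoRNA genes such as Mir1896, Snord16a and Snord32a, listed at 0 in every library of 1 group that was kept, and each call appeared only without the library that departs from its group. The 7 lists past the threshold became 0 with an estimated correlation and 0 with fry, where the smallest adjusted p was 0.6679. The count of lists ran from 5 to 16 with 1 library left out: 13 without control library 2 and 16 without control library 3. Camera takes no robust prior, so that alternative gave no count of lists. Of 19 alternatives per list, the actin and neutrophil lists passed in 17 and chemoattractant receptors in 16. Complement and immediate early genes passed in 14, and ribosomal and mast cell lists in 13. Over libraries, the two-sided exact permutation p of the list score was 0.2 for chemoattractant receptors and for complement. It was 0.3 for ribosomal and mast cell lists and 0.5 for immediate early genes.

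Equal replicate numbers did not pair the libraries: deviations from the group means correlated at -0.154, -0.0942 and -0.0235, and 0 libraries correlated best with their own number. With the replicate block 0 genes passed, and 11 lists did at the preset correlation, among them classical and non-classical monocyte, erythroid and fibroblast markers. With an estimated correlation and no block, limma's camera gave each of these named lists an adjusted p = 0.7311. Of 1320 combinations of a named gene and an alternative, 1306 kept their direction and side of the threshold and 14 reversed, all with 1 library left out. No named gene passed in any of these fits, and most were named for a small p in these data. The kept directions are therefore weak evidence of stability. The log2 fold change of 60 of the 120 named genes moved by over 1.5 times without at least 1 library, and that of 35 without control library 1. Lowest and highest log2 fold changes in those fits were -0.3242 and 0.3416 for Cx3cr1, -0.4833 and 0.0750 for Cd80, -0.1337 and 0.0859 for Csf1r, -0.0043 and 0.1646 for Srebf2, -0.4654 and 0.0836 for Vpreb1, -0.1341 and 0.1296 for Itga2b, -0.0770 and 0.6127 for Sparc and -0.3912 and 0.0014 for Mylpf. The mean of immediate early genes ran from -0.0769 to 0.3539. The cause of these reversals was not tested. At the estimated depth of 8510000 to 10400000 fragments, genes near 1 FPKM rest on few fragments, which limits Tnfrsf11a, Vpreb1 and Mylpf.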

Other observations

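The tests on secondary-granule genes, primary-granule genes, the 11 other cell type lists, the spread of the further neutrophil genes over libraries and control library 1 were chosen after their results were seen; the others were written before. The lists below did not pass the test with the values as deposited, no block and all 6 libraries. Of 34 oxidative phosphorylation genes 27 had a negative log2 fold change with a mean of -0.03 (limma camera, Benjamini-Hochberg adjusted p = 0.1189), and 21 of 32 lysosomal genes were negative with a mean of -0.04 (adjusted p = 0.1257). Oxidative phosphorylation passed as lower after quantile normalization (mean of -0.0449) and without CTLA4-Ig library 3 (-0.0463) or control library 2 (-0.0462), and lysosomal genes without control library 2 (-0.0697); with an estimated correlation and all 6 libraries both had an adjusted p = 0.7311. Of 34 cell cycle genes 23 were positive with a mean of 0.02 (adjusted p = 0.4959), and Birc5, which encodes survivin, stood at 166 ± 4.34 FPKM with CTLA4-Ig and 155 ± 11.01 with control IgG (SD, n = 3). Of 25 glycolysis and hypoxia genes 14 were positive with a mean of -0.01 (adjusted p = 0.6615, on the higher side in camera); Slc16a3, a lactate transporter gene, had a log2 fold change of 0.24 ± 0.06 (SE) and Pfkfb3 0.16 ± 0.07. The stress genes Ddit3 and Chac1 had 0.41 ± 0.11 and 0.36 ± 0.11, in a list with 9 of 21 members positive (adjusted p = 0.8646). Of the remaining tested lists 0 passed in camera at the preset correlation with all 6 libraries and no block: positive members were 6 of 10 Fc receptors, 8 of 13 genes of alternative activation, 8 of 17 phagocytosis, 11 of 27 cholesterol and lipid and 15 of 24 apoptosis genes. They were 4 of 9 B cell, 9 of 10 erythroid, 3 of 6 osteoblast, 5 of 5 fibroblast, 5 of 6 endothelial and 8 of 9 microglia markers. Some of these passed in other fits: erythroid markers with the replicate block (mean of 0.43) and without control library 2 (0.737) or 3 (0.728), fibroblast markers with the block (0.19) and without CTLA4-Ig library 1 (0.221) or control library 2 (0.254). Erythroid markers did not pass without control library 1. Their score was 1.65 in that library, 3.49 and 3.47 in the other controls and 3.09 to 3.52 with CTLA4-Ig. Endothelial markers passed without control library 3 (0.255), microglia markers without CTLA4-Ig library 1 (0.478) and cholesterol and lipid genes, as lower, without control library 2 (-0.0879). With an estimated correlation and all 6 libraries the adjusted p was 0.9692 for cholesterol and lipid genes and 0.7311 for the other 4. In the lists too short to test, 2 of 3 platelet, 1 of 4 muscle and 3 of 3 epithelial markers were positive.

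Among tissue macrophage markers, Folr2, Fcrls and Olfml3 were uneven across the CTLA4-Ig libraries, while Lyve1 was more even, at 1.29, 2.08 and 1.67 FPKM. The score of the macrophage list had an SD of 0.272 with CTLA4-Ig and 0.195 with control IgG (n = 3). That of the microglia list had 0.584 and 0.222. Folr2 stood at 1.26, 3.29 and 5.59 FPKM in the CTLA4-Ig libraries and 0.481, 1.11 and 1.85 in the controls. Fcrls and Olfml3, known from microglia and other resident macrophages, stood at 9.43 and 5.47 FPKM in CTLA4-Ig library 3 and at no more than 2.56 and 1.10 in the other 5. Fn1 stood at 782 FPKM in control library 1 and at 311 to 412 in the other 5 libraries.

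The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 0 genes past limma's adjusted threshold and the highest other split 2, so 10 of 10 splits gave as many, which a count of 0 fixes in advance. It gave 659 genes at an unadjusted p under 0.05, and the highest other, CTLA4-Ig library 1 with control libraries 2 and 3 against the rest, gave 1067, so 2 splits gave as many. It gave 7 lists, and the highest other split 19, so 9 of 10 splits gave as many. For neutrophil markers alone the camera p was 1.086e-09 in the real split, the smallest of the 10 (1 split as small), and 1.243e-06 in the next, CTLA4-Ig library 1 with control libraries 2 and 3, whose mean difference of 0.4743 was above the real 0.4631.

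Higher neutrophil markers with CTLA4-Ig may come from a larger share of neutrophil-lineage cells in the sorted gate or from a change within cells. The sort on EGFP would remove most neutrophils, which use little Cx3cr1, yet S100a8 and Ngp reached 95526 and 21790 FPKM. After quantile normalization the list's mean was 0.337 ± 0.0912 (SE over members, not libraries). That lay above the limit set beforehand, under which the authors' scaling would be the cause. The members share the same 6 libraries, so this test does not decide on that scaling. The mean was 0.466 after rescaling by the median of ratios. The factors of that rescaling, 0.998 to 1.004, show only that the values were already near its scale. The 4 primary-granule genes lay at -0.685 ± 0.0739 relative to the other 15 members. They are the 4 members with a negative log2 fold change and were set apart after their values were seen. The choice in part fixed that contrast, so it does not decide on a rise of all stages alike. A lower share of monocytes, taken to raise every other type and stage alike, stays open as the whole cause. The same contrast (-0.685 ± 0.162, SE over libraries) cannot decide it, for the same reason. The group difference of the neutrophil score exceeded that of NK cell markers, the most distant of 11 other cell type lists, by 0.622 ± 0.256. It exceeded the group difference of the mean score of the 11 by 0.319 ± 0.285 (both SE over libraries). A larger share of neutrophil-lineage cells, of later stages or of all, stays open too. The median log2 fold change of 27 further neutrophil genes was 0.303, with 23 positive and 4 at an unadjusted p under 0.05 in limma. A high quantile (not the maximum) of random lists matched on expression was 0.0442. Random lists do not carry the spread between libraries: the mean of the 27 genes differed between the groups by 0.302 ± 0.424 (SE over libraries), control library 1 lay above all CTLA4-Ig libraries in 13 of the 27, and the median was 0.576 without it. Monocytes also use some of these genes, and an effect of CTLA4-Ig on the cells themselves was not tested.

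The rise of actin cytoskeleton genes may belong to the same difference in cells. After quantile normalization the list's mean was 0.0635 ± 0.0202 (SE over members) against 0.0845. That cleared the limit set beforehand only narrowly, and the members share the same 6 libraries, so this test does not decide on the authors' scaling. Rescaling by the median of ratios left the mean at 0.0878. Its factors of 0.998 to 1.004 hardly changed the values, so it does not decide on the authors' scaling either. With the neutrophil score as a covariate, the test planned for this, the group difference was 0.10 ± 0.0466 (SE) against 0.0845 ± 0.0263 alone. Within groups the actin score changed with the neutrophil score by -0.034 ± 0.078 (SE). With 6 libraries that is too uncertain to exclude the neutrophil score as a source. A second covariate, tried after that result was seen, left a smaller estimate: with the mean of Ltf, Camp, Ngp, Lcn2 and Chi3l1 the difference was 0.00558 ± 0.0436. Those 5 genes were picked after their values were seen and their score does not overlap between the groups (11.87 to 12.27 against 11.24 to 11.56), so a share of cells with secondary granules and the treatment cannot be told apart here.

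Control library 1 stands apart from the other 5 libraries. Saa3, an acute phase gene, stood at 867 FPKM in it and at 16.5 to 50.7 in the others, and Chi3l3, a gene of alternatively activated macrophages, at 14245 against 4186 to 5521. With all members, 10 of 14 cell type lists lay beyond the range of the other 5 libraries. With members of a mean of at least 20 FPKM, 4 of 6 did. Few lists have enough abundant genes, so that test alone does not decide on lower depth. The depth of control library 1, 8620000 fragments, was not the lowest. CTLA4-Ig library 2, at 8510000 fragments, was at an extreme in 2 of the 14 lists. These depths argue against lower depth as the source of the 10 lists in control library 1. A different mix of cell types in this library may account for it: 9 of 14 cell type marker lists lay below the other 5 libraries and classical monocyte markers above, with erythroid markers lower by 1.72 on the log2 scale. Interferon-stimulated genes had a mean of 2.33 in it and 2.88 to 3.35 in the others. CTLA4-Ig library 3 was at an extreme in 8 of the 14 lists and control library 1 in 10, and no biological explanation for single libraries was tested.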
